A study of Oryza sativa with 10 samples.

How the data were processed

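The values were the signal intensities deposited by the authors, made with MAS5 (version not stated) from an Affymetrix rice genome array hybridized with biotin-labelled total RNA extracted with TRIzol. They were on a linear scale with 1 value per probe set and array, and each array already had a trimmed mean (2% to 98%) of 500. The array held 57381 probe sets, of which 123 controls were left out of the tests and used only as measures of quality. No detection calls, background values or scanner files were used.

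Each array was scaled to a 2% to 98% trimmed mean of 500, 16 was added and log2 taken. A probe set was tested if its signal was at least 100 on at least 2 of the 10 arrays, which left 30014. One limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 5 tissues was fitted, followed by eBayes with an intensity trend (5 residual and 5.14 prior degrees of freedom). A probe set was called at an adjusted p (Benjamini-Hochberg within a comparison) under 0.05 and at least a 2-fold difference. The 4 main comparisons were embryo minus endosperm, leaf minus root, seedling minus leaf and seedling minus root; the 4 of each seed part against leaf and root served the tissue-preferred sets. A probe set was tissue-preferred if called higher in 1 of embryo, endosperm, leaf and root against each of the other 3. The F-test across the 5 tissues was called at an adjusted p under 0.05. These choices and their alternatives were made before the data were examined. The replicate numbers did not pair samples across tissues (correlations of deviations from the tissue means from -0.108 to 0.0962), so no pairing was used.

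Probe sets were named by the gene identifiers of the array platform's annotation table and by a rice gene table (assembly ASM3414082v1) used only for symbols. Of all probe sets 22436 had 1 gene, 95 several and 34850 none; the tested ones with 1 gene covered 16420 genes, and 2837 tested probe sets had a readable symbol. Signals were given as the mean and SD over the 2 arrays of a tissue, without the added 16. Named genes were the 5 largest rises and 5 largest falls of each main comparison among those called with 1 gene and a readable symbol, with both arrays of one tissue above both of the other. To these came the 5 genes with the largest smallest difference in each tissue-preferred set and each seedling set, up to 3 rises, 3 falls and 1 member without a call in each list, and 27 genes known beforehand from rice seed and seedling biology.

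The 34 gene lists were: seed storage proteins, seed amylase and protease inhibitors, starch synthesis, sucrose cleavage and sugar transport, LEA proteins and seed maturation, ER protein folding, photosystems and light harvesting, Calvin cycle and photorespiration, chlorophyll and tetrapyrrole synthesis, aquaporins, mineral ion transporters, iron acquisition, phosphate starvation signalling, CASP-like membrane proteins, cell cycle and DNA replication, H2B histones and CenH3, ribosomal proteins, expansins, cellulose synthase superfamily, SPL transcription factors, auxin response factors, growth-regulating factors, NF-Y subunits, MADS-box factors, KNOX, WOX and HD-Zip factors, Aux/IAA proteins, JAZ proteins, auxin transport and conjugation, cytokinin metabolism and response, small RNA pathway, diterpenoid phytoalexins, heat shock proteins, lipid transfer proteins, and chitinases and germin-like proteins. Lists based on gene descriptions had been planned, but the gene tables at hand held no descriptions. Lists based on symbols were written in their place after the annotation, column summaries, array correlations and control values had been seen and before the values of any gene were. Planned lists of class III peroxidases, all core histones and defence proteins could not be formed as planned. Each list was tested with camera from limma at a preset correlation of 0.01, with 1 probe set per gene (the one with the highest mean) and at least 5 genes, and p was adjusted over the 34 lists of a comparison. Counts adjusted over the list alone used the Benjamini-Hochberg method within that list.

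The alternatives chosen before the data were examined were: a pseudocount of 1 or 64 or a floor of 32, quantile or median scaling, signals as deposited, no filter or a signal of 200, no trend, array weights, limma's treat against 2-fold, no fold minimum, an adjusted p under 0.01, only the tissues compared, a replicate block, and leaving out each array. For lists an estimated correlation, the mean over probe sets and leaving out cross-hybridizing (x or s) probe sets were added. Chosen after the data had been seen were scaling to the hybridization spike-ins (bioB, bioC, bioD and cre), the log2 Gapdh 3′ to 5′ ratio as a covariate, endosperm 1 and root 2 left out, and endosperm 2 and root 1 left out.

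The procedure was tested on simulated arrays with the mean and residual spread of each tested probe set and normal noise. Known differences were put into embryo, 50 per size: 2 (4%) were called at 2-fold, 15 (30%) at 4-fold, 41 (82%) at 8-fold and 43 (86%) at 16-fold, with 4 false calls and 0 in the wrong direction. Of 200 leaf-preferred probe sets put in at 8-fold 132 (66%) were found. A shifted list of 20 genes was called and 0 of 100 unshifted ones were. The simulation changed far fewer probe sets than were called in the data, which makes the adjusted p stricter. It also gave each tissue the same spread. Its shares found and false calls therefore need not hold for the real comparisons. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.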

Results

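Transcript levels were measured in 5 tissues of rice (Oryza sativa, japonica cultivar Zhonghua 11) with an oligonucleotide array of the rice genome, on which each gene is read by 1 or more sets of probes. Embryo and endosperm were taken from seeds 6 days after anthesis, leaf and root from 7-day-old seedlings, and the whole seedling at 10 days. Each tissue had 2 biological replicates with 1 array each, 10 arrays in all, and this number of arrays limits the precision. Signals below are means ± SD (n = 2 per tissue), and log2 differences are given ± SE from the limma fit over all 10 arrays. That fit holds 1 estimate of spread per probe set for all 5 tissues. The stated purpose was to profile these 5 tissues, so the comparisons asked which genes separate the seed parts, the seedling organs, and the whole seedling from its organs.

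The tissues differed at 21984 of the 30014 tested probe sets (73.2%) in limma's F-test. Across probe sets, which are not independent replicates, leaf and seedling were most alike (Pearson's r = 0.967 between tissue means) and endosperm and leaf least (0.770), with embryo and endosperm at 0.865. The first principal component (54.1% of the variance) parted the seed tissues from leaf, root and seedling, and the second (18.0%) parted embryo from endosperm. The 2 arrays of leaf (r = 0.980), seedling (0.975) and embryo (0.966) were closer than those of root (0.942) and endosperm (0.920), in which 25.01% and 26.2% of probe sets lay at least 2-fold apart. The 3′ to 5′ signal ratio of Gapdh, a measure of RNA and labelling quality, differed between tissues: it was 1.82 and 1.65 in embryo, 4.71 and 5.28 in endosperm, 26.3 and 29.1 in leaf, and 11.3 and 9.45 in seedling. The root arrays differed from each other, with 2.04 on root 1 and 24.0 on root 2. Endosperm 1 also had 3′ to 5′ ratios of 143 and 945 for the added dap and thr transcripts, against at most 7.23 and 8.85 on the other arrays.

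Each dissected tissue had transcripts higher than in the other 3 at the chosen threshold: 1602 probe sets (904 genes) in embryo, 2416 (1268) in endosperm, 1924 (1281) in leaf and 1225 (810) in root. In embryo the clearest were OsTDL1B (20074 ± 1302, next highest 357 in endosperm), MFT2 of the family that includes the flowering gene FT (24426 ± 4403, next 534.5 in root) and ETR4, an ethylene receptor (10008 ± 2826, next 224 in endosperm). In endosperm they were SAM2 (1774 ± 1101, next 34.6 in embryo), the seed protein gene RA17 (49880.3 ± 14390, next 2804 in embryo), ALK, the starch synthase SSIIa (28622 ± 4250.1, next 1762 in embryo), NF-Y4, an NF-YB subunit (14284 ± 2322, next 896 in embryo), and MADS24 (4533 ± 1280.2, next 291 in embryo). In leaf they were the germin-like genes GER8 (4514 ± 129, next 33.8 in root) and GER5 (14803 ± 493, next 214 in embryo), and GLT2 (2488 ± 866, next 29.7 in root). In root they were the amylase gene AMY1.1 (12500.5 ± 3537, at most 2.72 in the other 3), Lsi2, a silicon efflux transporter (5169 ± 787, at most 39.4), and the vacuolar aquaporin gene OsTIP2 (14470 ± 2932, at most 134). Adjusted p values of these 14 genes were at most 0.00568, the largest of each gene's 3 comparisons. Without embryo 1 the embryo set held 962 probe sets; without leaf 1 or leaf 2 the leaf set held 919 or 994 and the root set 580 or 628. The endosperm count depended on the scaling: it rose more than 1.5-fold with scaling to the median and fell more than 1.5-fold with scaling to the spike-ins.

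**Figure D1:**
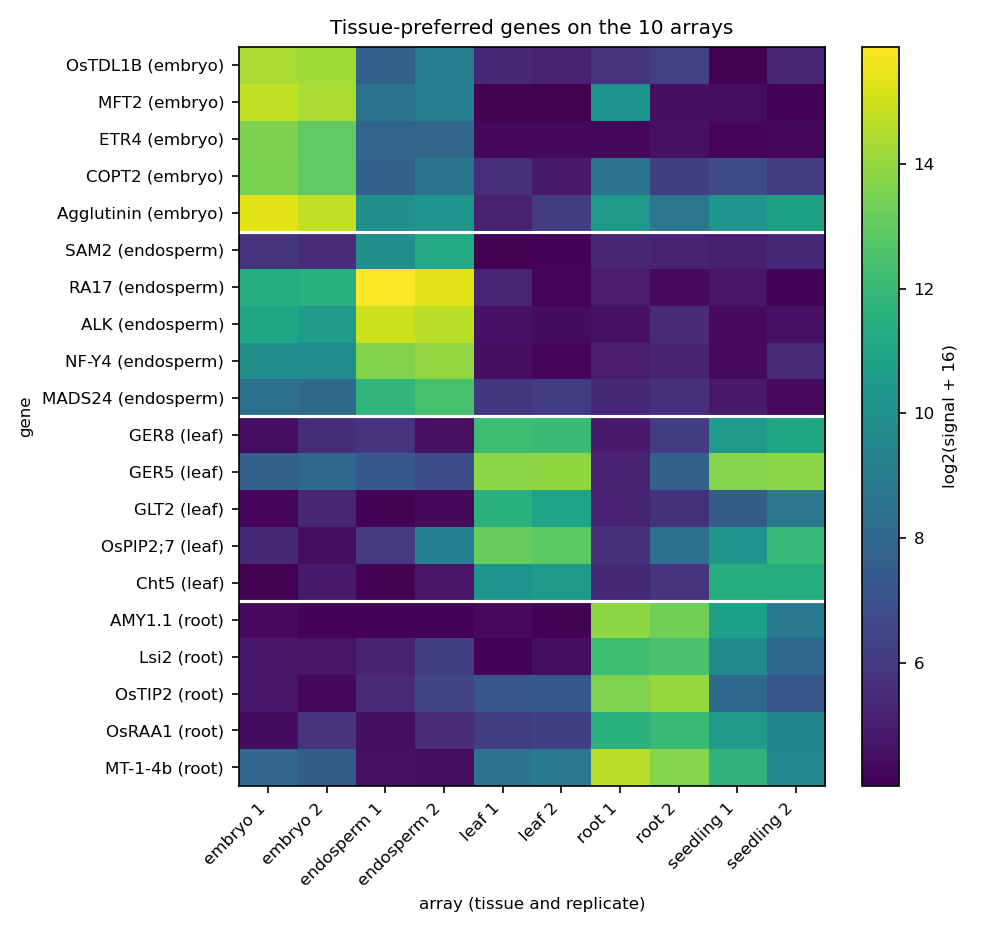
Heat map of the 20 tissue-preferred genes with the largest smallest difference, 5 each for embryo, endosperm, leaf and root, as log2(signal + 16) on each of the 10 arrays. Among the 4 dissected tissues each gene is brightest on both arrays of its own, as its choice required, for example AMY1.1 with 12500.5 in root and 2.25 in leaf. The seedling arrays show part of the leaf and root blocks, with Cht5 at 2648 in seedling against 1366 in leaf.

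Embryo and endosperm lie side by side in the same seed, and their comparison asked which genes separate the future plant from its nutritive tissue. Embryo had 6024 probe sets higher and 4881 lower than endosperm. The largest rises were of G1L2 (LOC4341811; 5455 ± 565 against 28.9 ± 5.28, log2 difference 6.93 ± 0.30), the cyclin gene CYCB2 (LOC4342121; 3919 ± 117 against 21.9 ± 27.5, 6.92 ± 0.57) and NAR2.2 (LOC4336175), whose family partners nitrate transporters (6305 ± 1182 against 53.8 ± 15.8, 6.51 ± 0.38). OSH1 (LOC4333973), a KNOX gene of the shoot meristem, had 1598 ± 211 against 4.39 ± 1.58 (6.30 ± 0.39), and pinA (LOC9268662) 17525 ± 3497 against 231 ± 127 (6.23 ± 0.36). The largest falls were of SAM2 (LOC4326996; 34.6 ± 6.53 against 1774 ± 1101, log2 difference -4.998 ± 0.49), the aquaporin gene OsPIP2;5 (LOC4343121; -4.90 ± 0.72), the cytokinin oxidase gene CKX5 (LOC4327887; -4.59 ± 0.62), MIF1 (LOC4349655; 673 ± 9.18 against 16737 ± 4568, -4.58 ± 0.48) and the nicotianamine synthase gene NAS1 (LOC4332608; -4.32 ± 0.42). Adjusted p values of these 10 genes ran from 3.42e-06 to 0.000506. In each both arrays of one tissue lay above both of the other, as the rule for naming required. Without embryo 1, 3227 probe sets were lower. The split between directions depended on the scaling: 55.2% of the called probe sets were higher in embryo as given, 42.4% (4993 higher, 6788 lower) with scaling to the median and 88.4% (10455 higher, 1371 lower) with scaling to the added spike-in transcripts.

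Of 5 lists of seed reserves and their making, the storage proteins were called and the other 4 were not. Of the 7 seed storage proteins tested, 5 fell from endosperm to embryo and 0 rose (5 and 0 adjusted over the list alone), with a median log2 difference of -1.92 and an adjusted p = 0.0428 in the list test (adjusted p = 0.762 with an estimated correlation). The glutelin gene GluC had 4982 ± 1546 against 35615 ± 7115 (-2.85 ± 0.38, adjusted p = 0.00028) and GLUA-1 10747 ± 2638 against 45014 ± 7737 (-2.08 ± 0.35, 0.0011), while GLB, at 3687 ± 223 against 2629 ± 438, did not pass. Of 14 starch synthesis genes 8 fell and 3 rose (8 and 4 adjusted over the list alone), which gave no list call (adjusted p = 0.16). The falls included ALK (1762 ± 379 against 28622 ± 4250.1, -4.02 ± 0.39) and AGPS2, a subunit of ADP-glucose pyrophosphorylase (6840.2 ± 338 against 35880.1 ± 9448, -2.36 ± 0.28), whereas GWD3, of a family that phosphorylates starch for breakdown, rose (1088 ± 81.9 against 185 ± 102, 2.55 ± 0.42). Among 26 genes of sucrose cleavage and sugar transport 6 rose and 7 fell (6 and 7 over the list alone, adjusted p = 0.704): the sucrose synthase gene OsSUS1 stood at 11225 ± 2206 against 537 ± 23.8 (4.33 ± 0.23) and OsSUS2 at 3017 ± 869.8 against 24734 ± 8600.3 (-3.01 ± 0.31), and the sugar exporter Os8N3, also named SWEET11, at 1401 ± 309 against 24996 ± 3507 (-4.15 ± 0.25). Of 12 seed amylase and protease inhibitors 5 rose and 6 fell (5 and 6 over the list alone, adjusted p = 0.75), with OC-I, a cystatin, at 2.85 ± 0.27 and RA17 at -4.12 ± 0.46; their median was -0.63, their mean 0.22 and the list test pointed down. Of 17 genes of protein folding in the endoplasmic reticulum 3 rose and 6 fell (3 and 6 over the list alone, adjusted p = 0.419), among them OsPDIL1-4, a disulfide isomerase (3559 ± 263 against 21375 ± 3123, -2.58 ± 0.28). The storage call ended without embryo 1 (median -1.72, adjusted p = 0.0744), endosperm 1 (-1.76, 0.094) or endosperm 2 (-2.01, 0.0637) and in 13 of 29 alternatives in all, and GLUA-1 lost its call with spike-in scaling.

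Embryo was higher for genes of cell division and of several families of regulators. All 10 growth-regulating factors, a plant family of transcription factors, rose (10 adjusted over the list alone), with GL2 at 9763 ± 2469 against 158 ± 8.06 (5.79 ± 0.38) and GRF1 at 2845 ± 110.1 against 83.0 ± 0.483 (4.85 ± 0.27). The list median was 3.76 (adjusted p = 1.66e-05, and adjusted p = 0.75 with an estimated correlation). Of 50 genes of the cell cycle and DNA replication 27 rose, 1 fell and 22 did not pass (28 and 2 adjusted over the list alone). Their median log2 difference was 1.30 (adjusted p = 5.81e-05, and adjusted p = 0.852 with an estimated correlation). The rises included CYCB2 and CYCD3-2 (3135 ± 1118 against 36.1 ± 17.7, 5.92 ± 0.42), and the fall was of CYCD5-2 (528 ± 59.3 against 3502 ± 1070.1, -2.66 ± 0.32). Of 25 Aux/IAA proteins, repressors in the auxin response, 14 rose and 2 fell (14 and 2 over the list alone), led by IAA31 (4041 ± 1735 against 60.4 ± 0.712, 5.66 ± 0.33) and IAA26 (4.94 ± 0.46). As a list their median was 1.18 (adjusted p = 0.00438, and adjusted p = 0.762 with an estimated correlation). Of 45 KNOX, WOX and HD-Zip factors 19 rose and 2 fell (20 and 3 over the list alone), with OsWOX6 at 4600.1 ± 277 against 120.1 ± 18.7 (5.09 ± 0.54). The median of the list was 0.74 (adjusted p = 0.01, and adjusted p = 0.852 with an estimated correlation). Of 12 late embryogenesis abundant (LEA) proteins and seed maturation genes 8 rose and 1 fell (8 and 1 over the list alone), with RAB16C at 9039 ± 303 against 332 ± 132 (4.75 ± 0.49), and VP1, a regulator of seed maturation, at 8152 ± 867 against 668 ± 208. The median over these genes was 2.63 (adjusted p = 0.00822, and adjusted p = 0.75 with an estimated correlation). MADS-box factors went mostly the other way: 12 of 20 fell and 3 rose (12 and 3 over the list alone), with AGL6 at 164 ± 61.1 against 2282 ± 1398 (-3.57 ± 0.51) and FST, also named MADS29, at 96.6 ± 53.4 against 1281 ± 291 (-3.59 ± 0.50). For the whole list the median was -1.64 (adjusted p = 0.0203, and adjusted p = 0.762 with an estimated correlation). Without endosperm 1 the cell cycle median was 0.86 (adjusted p = 0.000782) and the KNOX list was not called (0.56, 0.0601); without endosperm 2 neither the LEA list (2.25, 0.0527) nor the MADS-box list (-1.28, 0.0527) was called.

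The lists that follow were not called between embryo and endosperm. Auxin response factors had 8 of 17 rising and 2 falling (8 and 2 over the list alone, adjusted p = 0.16), with ARF2 at 7926 ± 678 against 327 ± 129 (4.58 ± 0.30). NF-Y subunits had 2 of 11 rising and 5 falling (2 and 5 over the list alone, adjusted p = 0.419), with HAP3 at 5448 ± 27.2 against 859 ± 238 (2.67 ± 0.29) and NF-Y4 at 896 ± 28.0 against 14284 ± 2322 (-3.96 ± 0.43). Among 27 genes of cytokinin metabolism and response 10 rose and 4 fell (10 and 4 over the list alone, adjusted p = 0.419), and among 14 of auxin transport and conjugation 6 rose and 1 fell (7 and 1 over the list alone, adjusted p = 0.528). Of 22 small RNA pathway genes 6 rose and 3 fell (6 and 3 over the list alone, adjusted p = 0.706), with DRB2 at 4.15 ± 0.42 and DRB4 at -2.41 ± 0.22. Of 22 CASP-like membrane proteins 6 rose and 5 fell (6 and 5 over the list alone, adjusted p = 0.917, median -0.04 and mean 0.01), and of 10 SPL transcription factors 2 rose (2 over the list alone, adjusted p = 0.706). The 7 genes of phosphate starvation signalling had 0 calls (0 over the list alone, adjusted p = 0.798), as had the 6 genes of H2B histones and CenH3 (1 rise over the list alone, adjusted p = 0.29), where H2B.11 stood at 12939.8 ± 503 against 7703 ± 1094. Of 11 photosystem and light harvesting genes 6 fell and 5 did not pass (7 over the list alone; median -2.73, adjusted p = 0.16), and their endosperm signals were uneven: the chlorophyll-binding protein gene CAB2R read 3028 on endosperm 1 and 24306 on endosperm 2, against 1149.6 and 714 in embryo. Its log2 difference was -3.22 ± 0.83 (adjusted p = 0.0111) and lost the call without endosperm 2 (-1.72, adjusted p = 0.0569) or embryo 2 (-2.88, adjusted p = 0.0791); the list was called without endosperm 1 (-4.06, adjusted p = 0.0177).

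Leaf and root, the 2 organs sampled at the same seedling age, were compared to ask which genes separate shoot from root. Leaf had 3274 probe sets higher and 2661 lower than root. The largest rises in leaf were of GER5 (LOC4345763; 14803 ± 493 against 104 ± 119, 7.43 ± 0.62), GER8 (LOC4325743; 6.64 ± 0.59), the aquaporin gene OsPIP2;7 (LOC4347729; 5.94 ± 1.05), GLT2 (LOC4339561; 5.76 ± 0.55) and PCF7, a TCP transcription factor (LOC4325137; 3645 ± 155 against 53.4 ± 2.09, 5.72 ± 0.36). The largest falls were of AMY1.1 (LOC4330832; 2.25 ± 2.71 against 12500.5 ± 3537, -9.40 ± 0.53), Lsi2 (LOC4331328; 4.06 ± 3.35 against 5169 ± 787, -8.02 ± 0.56), the aluminium transporter gene Nrat1 (LOC4328200; 28.8 ± 2.19 against 4913 ± 1184, -6.76 ± 0.53), OsTIP2 by another of its probe sets (LOC4330207; -6.70 ± 0.65) and the dehydrin gene RAB16D (LOC4350451; -5.65 ± 0.55). Adjusted p values of these 10 genes ran from 1.56e-05 to 0.00313, with both arrays of one organ above both of the other, as required for naming. Without leaf 1 the counts were 1573 and 1125, and without leaf 2 they were 1621 and 1195; scaling to the median gave 2953 higher and 3555 lower (45.4% higher, against 55.2% as given).

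The 3 chloroplast lists were called higher in leaf. Of 16 genes of chlorophyll and tetrapyrrole synthesis 14 rose and 0 fell (15 and 0 adjusted over the list alone), with PPO at 3322 ± 375 against 306 ± 27.4 (3.37 ± 0.38) and CHL1 at 3913 ± 154 against 430.1 ± 67.7 (3.15 ± 0.32). Here the median difference was 1.99 (adjusted p = 2.19e-07, and adjusted p = 0.415 with an estimated correlation). Of 11 Calvin cycle and photorespiration genes 8 rose (8 over the list alone), among them the Rubisco activase gene OsrcaA1 (20751 ± 2034 against 1381 ± 149.5, 3.89 ± 0.41) and the chloroplast glutamine synthetase gene GLN2 (14641 ± 1181 against 954 ± 551, 4.04 ± 0.62). The list median was 2.48 (adjusted p = 0.00496, and adjusted p = 0.574 with an estimated correlation). Of 11 photosystem and light harvesting genes 5 rose (9 over the list alone). Their median log2 difference was 2.97 (adjusted p = 0.000398, and adjusted p = 0.574 with an estimated correlation). The ferredoxin-NADP reductase gene LFNR1 was at 10925 ± 1390.3 against 481 ± 327 (4.63 ± 0.52), while CAB2R, at 19700.5 ± 2004 against 9744 ± 8157, did not pass. The 2 root arrays differed in these genes: CAB2R read 15512 on root 1 and 3976 on root 2, and the median signal of the 11 genes 3227 and 351. Without root 2 the photosystem median was 1.55 (adjusted p = 0.0473) and the Calvin list was not called (1.61, adjusted p = 0.0566).

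**Figure D2:**
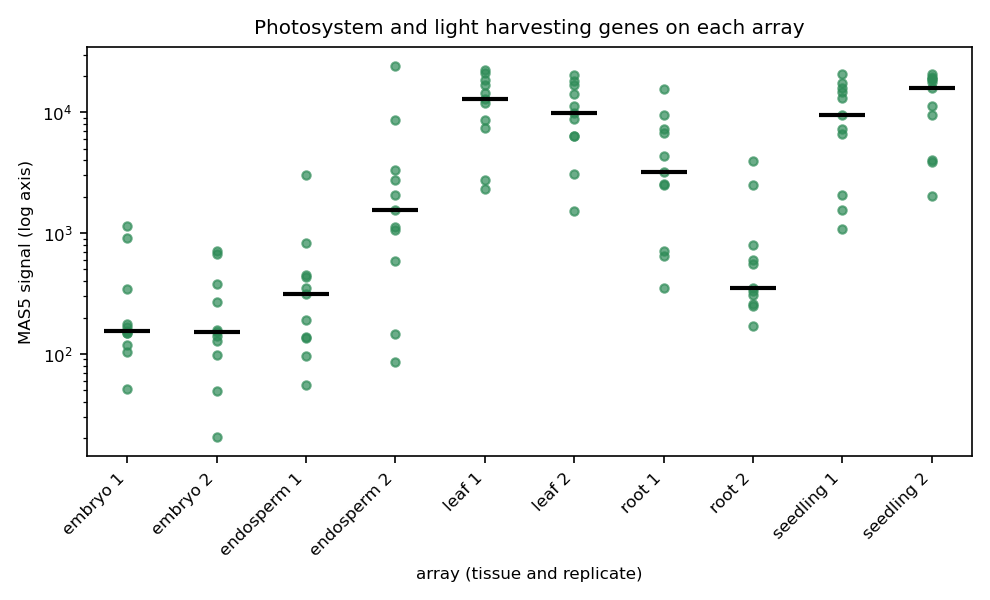
Signal intensity on a log axis of the 11 photosystem and light harvesting genes on each of the 10 arrays, 1 point per gene and a black dash at the median. The medians were 12916 and 9942 in leaf, 9563 and 15751 in seedling, 155 and 152 in embryo, but 310.4 on endosperm 1 against 1547 on endosperm 2, and 3227 on root 1 against 351 on root 2.

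The other 6 lists called between leaf and root were lower in leaf. Of 73 mineral ion transporters 20 fell from root to leaf and 4 rose (22 and 6 adjusted over the list alone), with the silicon channel gene Lsi1 at 902 ± 123 against 17692 ± 108 (-4.28 ± 0.54). As a list their median was -0.66 (adjusted p = 0.00593, and adjusted p = 0.574 with an estimated correlation). Of 13 genes of diterpenoid phytoalexin synthesis 8 fell (9 over the list alone), with CPS4 at 106 ± 47.6 against 1738 ± 489 (-3.87 ± 0.59) and CYP99A3 at 188 ± 93.8 against 2777 ± 778 (-3.82 ± 0.46). The median of the list was -2.34 (adjusted p = 0.000346, and adjusted p = 0.541 with an estimated correlation). Of 12 LEA and maturation genes 5 fell (6 over the list alone), with RAB16D at 28.2 ± 8.50 against 2211 ± 543. The median over these genes was -1.02 (adjusted p = 0.00201, and adjusted p = 0.415 with an estimated correlation). Of 22 heat shock proteins 6 fell (6, and 1 rise, over the list alone), with HSP16.9A at 101 ± 28.5 against 2883 ± 1842 (-4.49 ± 0.40). For the whole list the median was -0.68 (adjusted p = 0.0201, and adjusted p = 0.541 with an estimated correlation). Of 12 amylase and protease inhibitors 3 fell (4 over the list alone), among them RA14 (35.7 ± 13.1 against 209 ± 45.3). Here the median difference was -0.85 (adjusted p = 0.00705, and adjusted p = 0.415 with an estimated correlation). Ribosomal proteins were lower as a list (median -0.56, adjusted p = 0.0021, and adjusted p = 0.611 with an estimated correlation), although of 24 only RPS26 fell (-1.36 ± 0.25) and CL18 (2.68 ± 0.46) and CL27 (2.42 ± 0.29), of the chloroplast ribosome, rose (2 and 1 over the list alone). Without root 1 neither the mineral ion list (-0.49, adjusted p = 0.143) nor the inhibitors (-0.63, 0.0929) were called. Both calls also ended with the Gapdh ratio as a covariate, that of the inhibitors also without cross-hybridizing probe sets, and the heat shock call with quantile normalization.

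Some lists were not called between leaf and root, yet held large differences. Aquaporins had 7 of 23 falling and 3 rising (8 and 3 adjusted over the list alone, adjusted p = 0.0616), with OsPIP1;3 at 412 ± 124 against 8866 ± 4026 (-4.33 ± 0.44) and NIP1-1 at 10991 ± 135 against 662 ± 372 (4.14 ± 0.36). Of 12 chitinases and germin-like proteins 4 rose and 5 fell (4 and 7 over the list alone, adjusted p = 0.9; median -1.35, mean 0.44, list test down). Of 22 CASP-like proteins 7 fell and 3 rose (7 and 3 over the list alone, adjusted p = 0.569), with OsCASP1, of the family that builds the Casparian strip of the root endodermis, at 18.7 ± 14.7 against 1014 ± 230.0 (-4.94 ± 0.50). Of 45 KNOX, WOX and HD-Zip factors 8 rose and 10 fell (10 and 10 over the list alone, adjusted p = 0.951), with GL2-1, also named ROC1, an epidermal homeobox gene, at 3156 ± 122 against 211 ± 94.7 (3.87 ± 0.34). Of 23 expansins, which loosen cell walls, 6 fell and 1 rose (7 and 2 over the list alone, adjusted p = 0.172). The median, mean and test of further lists without a call differed in sign: cell cycle (0.04, 0.01, test down), NF-Y subunits (-0.33, 0.11, test down), SPL transcription factors (-0.06, 0.36, test up) and JAZ proteins (0.06, -0.03, test down).

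The whole seedling was compared with leaf and with root to ask where it departs from its organs. It was also 3 days older, so age and plant part change together. Against leaf, 591 probe sets were higher and 221 lower in the seedling, and against root 3324 and 2370. The largest rises over leaf were of ICL, isocitrate lyase of the glyoxylate cycle (LOC4343441; 4693 ± 229 against 32.3 ± 11.9, 6.63 ± 0.63), the haemoglobin gene NSHB1 (LOC4332166; 1599.5 ± 257 against 11.7 ± 1.35, 5.86 ± 0.88), AMY1.1 (1075 ± 828 against 2.25 ± 2.71, 5.66 ± 0.53), NSHB2 (LOC4332123; 5.11 ± 0.84) and LEA19 (LOC4339480; 5141 ± 872 against 154 ± 108, 5.08 ± 0.42). The largest falls were of Nramp1, a metal transporter gene (LOC4342862; 132 ± 38.9 against 10003 ± 2652, -6.08 ± 0.39), BURP2 (LOC4338119; -5.56 ± 0.88), NAS2 (LOC4332607; 351 ± 198 against 9489 ± 1538, -4.80 ± 0.51), mfs1 (LOC4326904; -4.36 ± 0.50) and NAS1 (-4.02 ± 0.42). Adjusted p values of these 10 ran from 0.00021 to 0.0108; NSHB1, NSHB2 and BURP2 lost their calls without any one of the 4 leaf and seedling arrays (adjusted p 0.0512 to 0.113). Over root the largest rises were of GER5 (13562 ± 931 against 104 ± 119, 7.31 ± 0.62), BURP16 (LOC4348595; 17491 ± 83.5 against 143 ± 3.73, 6.78 ± 0.49), the glutaredoxin gene GRXC1 (LOC4325734; 6.76 ± 0.42), Cht5 (LOC4336265; 5.76 ± 0.41) and GLK2, a regulator of chloroplast development (LOC4326363; 4167 ± 1401 against 76.9 ± 31.2, 5.49 ± 0.38). The largest falls were of PRX112 (LOC4344279; -6.68 ± 0.76), OsTIP2 (-6.52 ± 0.65), NAS2 (351 ± 198 against 24415 ± 7361, -6.14 ± 0.51), NAS1 (609 ± 245 against 19272 ± 119, -5.01 ± 0.42) and the expansin gene EXPB2 (LOC4349348; -4.96 ± 0.74), with adjusted p values of these 10 from 2.59e-05 to 0.00173. In all 20 cases both arrays of one tissue lay above both of the other, which was a condition for being named.

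Both sets of counts depended on single arrays, and a tissue left with 1 array is assumed to spread like the others. Against leaf, the higher and lower counts were 131 and 37 without leaf 1, 165 and 42 without leaf 2, 82 and 32 without seedling 1, and 212 and 76 without seedling 2. They were 891 and 377 without root 1 and 892 and 375 without root 2, and the lower count was 135 or 137 without embryo 1 or embryo 2 and 392 or 395 without endosperm 1 or endosperm 2. Against root they were 1819 and 1330 without seedling 1 and 1101 and 779 without seedling 2. Scaling to the median turned the split against root to 2743 higher and 3339 lower (45.1% higher, against 58.4% as given).

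The lists called higher in the seedling than in leaf were these 5. Of 13 phytoalexin genes 7 rose (10 adjusted over the list alone), with CYP99A3 at 1777 ± 457 against 188 ± 93.8 (3.19 ± 0.46), which lost its call without leaf 1 (2.70, adjusted p = 0.0751) or seedling 1 (2.93, adjusted p = 0.103). The list median was 2.52 (adjusted p = 8.05e-10, and adjusted p = 0.116 with an estimated correlation). Of 22 heat shock proteins 7 rose (11 over the list alone), with HSP18.0 at 12456 ± 1902 against 674 ± 78.6 (4.17 ± 0.38) and HSP24.1 at 4912 ± 505 against 363 ± 78.7 (3.71 ± 0.44). Their median log2 difference was 1.08 (adjusted p = 3.03e-09, and adjusted p = 0.0778 with an estimated correlation). Of 12 LEA and maturation genes 7 rose and 2 fell (7 and 2 over the list alone), with RAB16B at 1862 ± 703 against 175 ± 56.9 (3.28 ± 0.35). As a list their median was 2.38 (adjusted p = 6.6e-05, and adjusted p = 0.0778 with an estimated correlation). Of 12 chitinases and germin-like proteins 3 rose (3 over the list alone), and GER5, at 13562 ± 931 against 14803 ± 493, did not pass. The median of the list was 1.01 (adjusted p = 0.023, and adjusted p = 0.38 with an estimated correlation). Of 23 aquaporins 3 rose (5, and 1 fall, over the list alone). The median over these genes was 0.36 (adjusted p = 0.0211, and adjusted p = 0.524 with an estimated correlation). The chitinase call ended with a pseudocount of 1 and without the cross-hybridizing probe sets, and without seedling 1 the aquaporin median was 0.23 (adjusted p = 0.0296).

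The seedling was lower than leaf in 4 lists. Of 19 iron acquisition genes 5 fell (7 adjusted over the list alone), NAS1 and NAS2 among them. For the whole list the median was -0.57 (adjusted p = 0.000538, and adjusted p = 0.113 with an estimated correlation). Of 12 JAZ proteins, repressors of the jasmonate response, 1 fell (3 over the list alone), and EG2, at 10407 ± 1303 against 15777 ± 111, did not pass. Here the median difference was -0.60 (adjusted p = 7.57e-05, and adjusted p = 0.0778 with an estimated correlation). Of 23 expansins 1 fell (3 over the list alone), and EXPB3 stood at 2872 ± 522 against 8406 ± 1243 without passing. The list median was -0.60 (adjusted p = 0.00485, and adjusted p = 0.524 with an estimated correlation). Of 25 genes of the cellulose synthase superfamily 1 fell (1, and 1 rise, over the list alone). Their median log2 difference was -0.44 (adjusted p = 0.0222, and adjusted p = 0.524 with an estimated correlation). With the Gapdh ratio as a covariate the photosystem, Calvin cycle and chlorophyll lists were also called lower in the seedling, and without seedling 2 so was the gene list chlorophyll and tetrapyrrole synthesis, seedling minus leaf (-0.69, adjusted p = 0.0125). The cellulose call ended without leaf 2 (-0.30, adjusted p = 0.107) or seedling 1 (-0.33, 0.0639) and without the signal filter. Median and mean differed in sign in 3 lists without a call: storage proteins (-0.11, 0.02), photosystems (0.07, -0.15) and H2B histones (0.18, -0.02).

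Against root, 4 lists were called higher in the seedling, 3 of them of the chloroplast. Of 16 chlorophyll and tetrapyrrole genes 11 rose (12 adjusted over the list alone), with PORA, a protochlorophyllide reductase, at 1212 ± 534 against 73.1 ± 43.3 (3.80 ± 0.56). As a list their median was 1.97 (adjusted p = 4.08e-06, and adjusted p = 0.439 with an estimated correlation). Of 11 photosystem genes 6 rose (9 over the list alone). The median of the list was 2.98 (adjusted p = 0.000703, and adjusted p = 0.563 with an estimated correlation). Of 11 Calvin cycle genes 8 rose and 1 fell (8 and 1 over the list alone), with OsrcaA1 at 23926 ± 2681 against 1381 ± 149.5 (4.10 ± 0.41). The median over these genes was 2.02 (adjusted p = 0.0142, and adjusted p = 0.619 with an estimated correlation). Of 5 lipid transfer proteins 2 rose (3 over the list alone), with LTP110-A at 13419 ± 1153 against 2085 ± 1463 (2.87 ± 0.40). For the whole list the median was 1.07 (adjusted p = 0.029, and adjusted p = 0.439 with an estimated correlation). Without root 2 the Calvin (1.56, adjusted p = 0.145), photosystem (1.49, 0.07) and lipid transfer (0.78, 0.07) lists were not called, and the lipid transfer call also ended with spike-in scaling.

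Lists lower in the seedling than in root covered walls, iron and other ions. Of 23 expansins 12 fell and 2 rose (12 and 2 adjusted over the list alone), with EXP3 at 31.8 ± 7.56 against 1569 ± 1199 (-4.82 ± 0.62). Here the median difference was -1.13 (adjusted p = 0.00223, and adjusted p = 0.544 with an estimated correlation). Of 19 iron acquisition genes 9 fell and 1 rose (10 and 1 over the list alone), with the iron transporter gene IRT1 at 68.3 ± 22.6 against 1387 ± 240.3 (-4.07 ± 0.41). The list median was -1.54 (adjusted p = 0.00377, and adjusted p = 0.374 with an estimated correlation). Of 73 mineral ion transporters 16 fell and 4 rose (17 and 4 over the list alone). Their median log2 difference was -0.61 (adjusted p = 0.00586, and adjusted p = 0.551 with an estimated correlation). JAZ proteins had 2 of 12 falling (2 over the list alone). As a list their median was -0.76 (adjusted p = 0.00414, and adjusted p = 0.374 with an estimated correlation). Amylase and protease inhibitors had 3 of 12 falling (3 over the list alone). The median of the list was -0.43 (adjusted p = 0.0446, and adjusted p = 0.516 with an estimated correlation). Ribosomal proteins had 2 of 24 falling and CL18 and CL27 rising (2 and 2 over the list alone). The median over these genes was -0.62 (adjusted p = 0.000519, and adjusted p = 0.563 with an estimated correlation). Without root 1 the mineral ion list was not called (-0.35, adjusted p = 0.211), nor were the inhibitors without embryo 1 (-0.43, 0.053), embryo 2 (-0.43, 0.0528), root 1 (-0.27, 0.297) or seedling 2 (-0.36, 0.0576) and in 15 of 29 alternatives in all. Median and mean differed in sign in 3 lists without a call: storage proteins (0.03, -0.11), NF-Y subunits (-0.13, 0.24) and KNOX factors (-0.03, 0.11).

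The seedling was next asked for transcripts above or below both of its sampled organs, which 252 and 107 probe sets were. As the seedling arrays serve in both comparisons, some overlap can come by chance. Independent lists would share 65.5 and 17.5, a value that leaves the shared arrays out of account. Simulations with equal means in leaf, root and seedling gave 0 and 0, which the threshold nearly ensures. Neither is thus a chance level for 252 and 107. Simulations of a seedling that mixes leaf and root in equal parts gave means of 4.30 and 2.05. Such a mixture lies between leaf and root for each probe set, which nearly ensures low counts. These means show only what independent noise adds to it, and are no chance level either. Above both were GRXC15 (LOC4352426; 2382 ± 524 against 107 in leaf and 55.2 in root), CPDK2 (LOC4333181; 1539 ± 114 against 67.0 and 71.9), BURP16 (17491 ± 83.5 against 2399 and 143), ICL (4693 ± 229 against 32.3 and 837), and HSF24 of the heat shock factor family (LOC4347637; 2817 ± 287 against 145 and 422). Below both were BURP2 (108 ± 8.08 against 6215 and 5068), NAS2 (351 ± 198 against 9489 and 24415), NAS1 (609 ± 245 against 9758 and 19272) and Nramp1 (132 ± 38.9 against 10003 and 2237). Adjusted p values of these 9 genes were at most 0.0111, the larger of each gene's 2 comparisons. By list, 5 of 22 heat shock proteins and 3 of 12 LEA genes lay above both, and 5 of 19 iron acquisition genes, 2 LEA genes and 2 of 73 mineral ion transporters below both. Above both stood 77 probe sets without leaf 1, 82 without leaf 2, 41 without seedling 1 and 59 without seedling 2. Below both stood 26, 27, 21 and 33 in that order, and 174, 176 and 167 without endosperm 1, endosperm 2 and root 2.

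**Figure D3:**
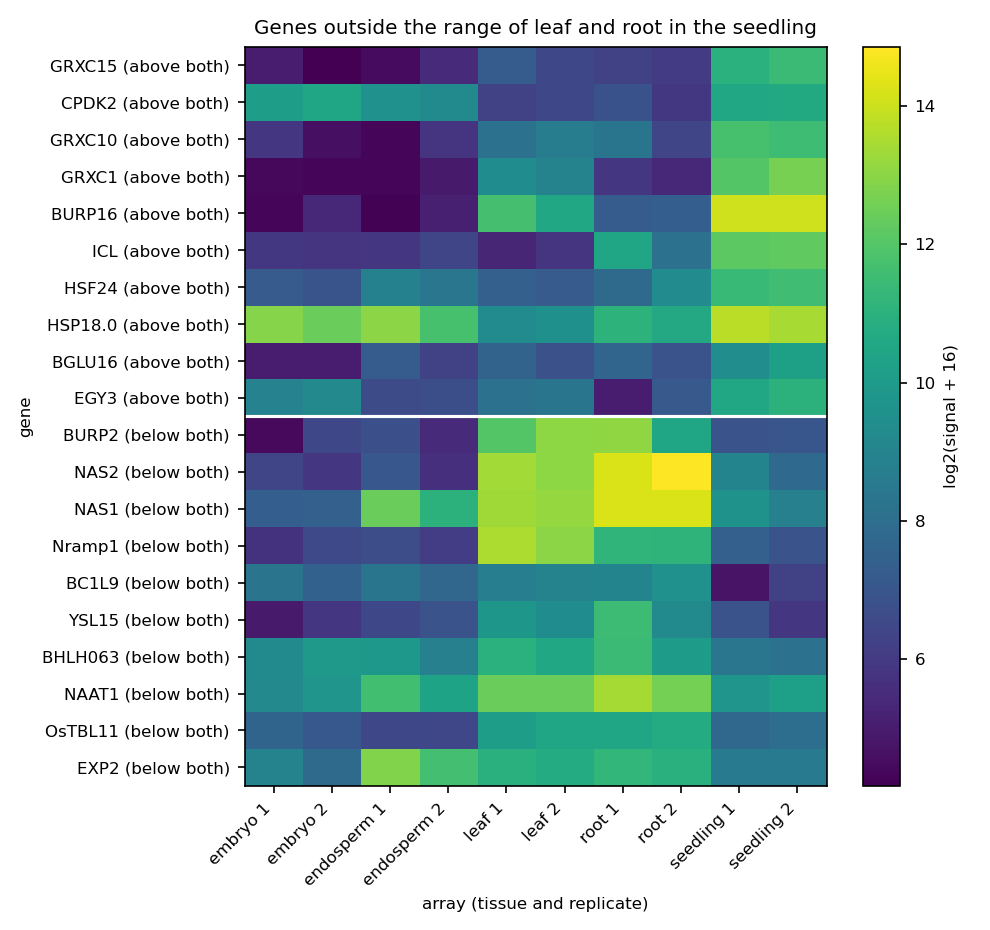
Heat map of the 10 genes highest above and the 10 lowest below both leaf and root in the seedling, as log2(signal + 16) on each of the 10 arrays. GRXC15 read 2382 in seedling against 107 in leaf, and NAS2 351 against 9489.

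Across the seed and seedling tissues, each seed part differed from each organ at more probe sets than leaf from root. Embryo had 5491 higher and 7068 lower than leaf, and 4622 and 5668 than root. Endosperm had 6549 and 9282 against leaf, and 5297 and 7923 against root, where the median over all tested probe sets was itself shifted by -0.20 and -0.14. Storage proteins were endosperm-preferred for 5 of 7 genes, starch synthesis for 7 of 14, protein folding in the endoplasmic reticulum for 5 of 17 and MADS-box factors for 7 of 20. Embryo-preferred were 7 of 10 growth-regulating factors and 7 of 12 LEA genes, leaf-preferred 8 of 11 Calvin cycle and 8 of 16 chlorophyll genes, and root-preferred 8 of 13 phytoalexin genes and 12 of 73 mineral ion transporters. The DNA methyltransferase gene MET1 was highest in endosperm, with 801 ± 104 in embryo, 4120.3 ± 2675.5 in endosperm, 902 ± 47.4 in leaf and 681 ± 325 in root. Without embryo 1, embryo stood above root at 3041 probe sets. With scaling to the median the larger side turned in all 4 of these comparisons: 8332 were higher and 5290 lower in embryo than in leaf, 6231 and 4823 than in root, and 10750 and 6339 in endosperm than in leaf, 9067 and 5772 than in root.

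**Figure D4:**
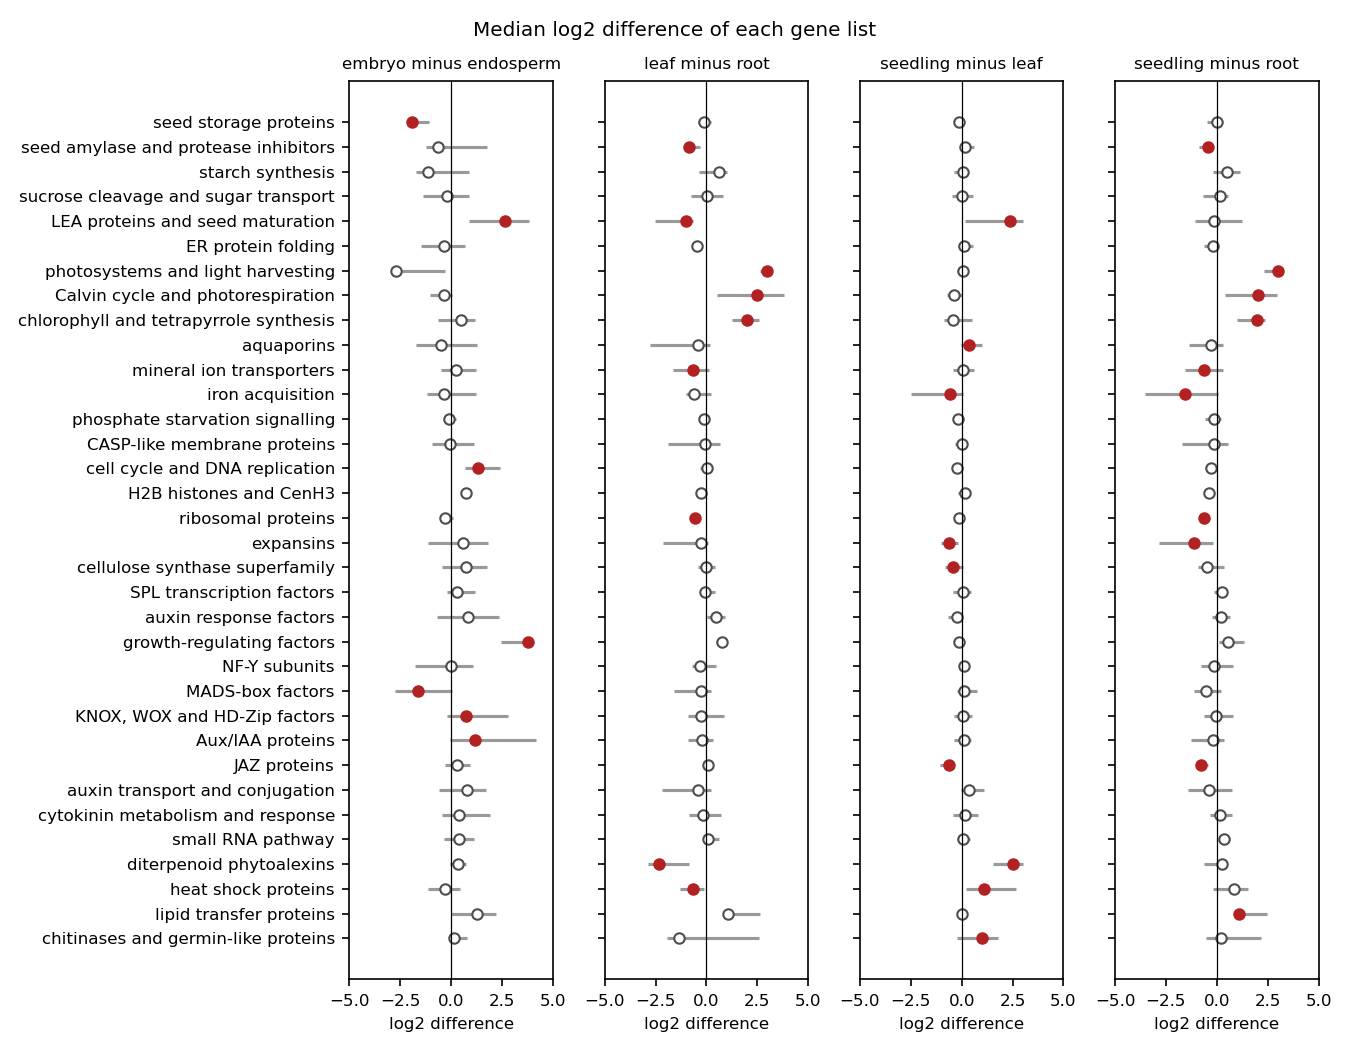
Median log2 difference with quartile bars of the 34 gene lists in 4 comparisons, filled red where the list test gave an adjusted p under 0.05. In embryo against endosperm the growth-regulating factors were highest among the called lists, with a median of 3.76, and the storage proteins lowest, with -1.92.

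Of the 136 list tests in these 4 comparisons, 35 were called with the preset correlation and 0 with a correlation estimated from the 10 arrays, whose adjusted p values for those 35 ran from 0.0778 to 0.852. Most of the 35 had an estimate over the preset 0.01, but a larger correlation was not needed to lose a call. JAZ proteins in seedling minus leaf had an estimate of 0.00467, yet their camera p rose from 8.9e-06 to 0.00603. Starch synthesis in embryo minus endosperm, a list without a call, had an estimate of -0.0103, and its camera p rose from 0.0381 to 0.0786. The 0 calls in this setting are thus not a measure of the correlation of the genes alone. The lists were written from gene symbols after the annotation and control values had been seen and before the values of their genes were, so they were not fixed in advance.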

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

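All counts below are probe sets. Of 23 counts (22 with no fold minimum), 0 moved more than 1.5-fold with a floor of 32, quantile normalization, signals as deposited (the same values), a signal of 200 on 2 arrays, no trend, no fold minimum or a replicate block (embryo minus endosperm: probe sets higher 5987, against 6024), and 0 called results of genes or lists reversed direction in any setting. The larger side of a comparison's counts did turn with median scaling, and medians of lists without a call changed sign, as for the seed amylase and protease inhibitors in embryo minus endosperm (-0.63, and 0.33 with spike-in scaling).

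A stricter threshold lowered counts by construction. With limma's treat against 2-fold, the higher and lower counts were 2730 and 1459 in embryo minus endosperm, 1124 and 697 in leaf minus root, 136 and 38 in seedling minus leaf, 760 and 389 in seedling minus root, 2167 and 3411 in embryo minus leaf, 1715 and 2919 in embryo minus root, 2869 and 5278 in endosperm minus leaf, and 2092 and 4204 in endosperm minus root. The sets held 551 embryo-preferred probe sets, 756 endosperm-preferred probe sets, 616 leaf-preferred probe sets and 356 root-preferred probe sets; for the seedling above both leaf and root: probe sets 38, and below both leaf and root 18. With an adjusted p under 0.01, embryo minus endosperm had 3118 lower, leaf minus root 1925 and 1342, seedling minus leaf 222 and 74, seedling minus root 1615 and 1128, the preferred sets 1034 (embryo), 1568 (endosperm), 1100 (leaf) and 597 (root), and the seedling 80 above and 41 below both.

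Scaling moved counts and the cause was not tested. Median scaling turned the larger side in embryo minus endosperm (4993 higher, 6788 lower), leaf minus root (2953, 3555), seedling minus root (2743, 3339), embryo minus root (6231, 4823), embryo minus leaf (8332, 5290), endosperm minus leaf (10750, 6339) and endosperm minus root (9067, 5772), and gave 4162 endosperm-preferred probe sets; the median over all probe sets became 0.33, 0.49 and 0.40 in the last 3. Spike-in scaling gave 10455 and 1371 in embryo minus endosperm (median over all 0.80), 2206 and 14617 in endosperm minus leaf (-1.18), 1762 and 13468 in endosperm minus root (-1.08), 682 endosperm-preferred, 1624 lower in leaf minus root, 291 and 99 in seedling minus leaf, 1461 lower in seedling minus root, and 127 above and 48 below both organs.

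Other settings moved fewer counts, and the cause was not tested. Pseudocount 1 gave 123 lower in seedling minus leaf and 161 above both, pseudocount 64 gave 349 lower in seedling minus leaf, and no filter 145. Array weights gave 2198 and 1396 in seedling minus leaf, 3268 higher in endosperm minus root, and 508 above and 299 below both. Only the tissues compared gave 1941 and 1264 in seedling minus leaf, 2070 and 1532 in seedling minus root, 3371 higher in endosperm minus root, and 445 above and 243 below both. The Gapdh ratio covariate gave 3399 and 4361 in embryo minus leaf, 424 lower in seedling minus leaf and 761 root-preferred probe sets. With endosperm 1 and root 2 left out, leaf minus root had 5389 and 4614, seedling minus leaf 1852 and 1166, seedling minus root 5433 and 4112, root-preferred probe sets 2031, and for the seedling above both leaf and root: probe sets 695, below both 400. With endosperm 2 and root 1 left out, seedling minus leaf had 1854 and 1157, and 744 above and 364 below both.

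Leaving out 1 array gave these lowest and highest counts (array left out). Embryo minus endosperm: higher 4399 (embryo 2) to 7007 (endosperm 2), lower 3227 (embryo 1) to 5264 (root 1). Leaf minus root: higher 1573 (leaf 1) to 3964 (root 2), lower 1125 (leaf 1) to 3287 (root 2). Seedling minus leaf: higher 82 (seedling 1) to 892 (root 2), lower 32 (seedling 1) to 395 (endosperm 2). Seedling minus root: higher 1101 (seedling 2) to 4000 (endosperm 2), lower 779 (seedling 2) to 2922 (endosperm 2). Embryo minus leaf: higher 3877 (leaf 1) to 5968 (endosperm 2), lower 4972 (leaf 1) to 7610 (endosperm 1). Embryo minus root: higher 3041 (embryo 1) to 5050 (endosperm 2), lower 4165 (embryo 1) to 6194 (endosperm 1). Endosperm minus leaf: higher 5043 (leaf 1) to 6767 (root 1), lower 7372 (leaf 1) to 9782 (endosperm 2). Endosperm minus root: higher 4889 (leaf 2) to 5378 (endosperm 1), lower 6829 (endosperm 1) to 8859 (endosperm 2). Differing among tissues: 18837 (embryo 1) to 23423 (root 2). Preferred: embryo 962 (embryo 1) to 1770 (endosperm 2), endosperm 1838 (embryo 1) to 2463 (endosperm 2), leaf 919 (leaf 1) to 2233 (endosperm 2), root 580 (leaf 1) to 1533 (root 2). Seedling above both leaf and root 41 (seedling 1) to 370 (endosperm 2), below both 21 (seedling 1) to 176 (endosperm 2). Fewer arrays give a less sure estimate of spread; other causes were not tested.

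Of 136 list results, 35 lost their call with an estimated correlation, 1 with the mean over probe sets, 3 with quantile normalization, 2 with spike-in scaling, 4 with the Gapdh ratio covariate and 0 with a replicate block; 4 of 132 were lost without x or s probe sets. Leaving out 1 array lost 0 to 4 of them, and the 2 pairs of arrays 4 and 7. Of 637 results of named genes, 211 lost their call with treat against 2-fold, 92 with spike-in scaling, 56 with only the tissues compared, 10 with a replicate block, and 18 to 95 when 1 array was left out.

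Limits remain. Signals are intensities that include background and cross-hybridization, so ratios with a low signal are rough and no copy numbers follow. With 2 arrays per tissue the SD is uncertain. Small differences were rarely found in the test with known differences (4% at 2-fold). That test changed far fewer probe sets than were called in the data, so its share is no estimate for the real comparisons.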

Other observations

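The 2 root arrays differed in some genes of the circadian clock and of nutrient uptake, chosen after their values were seen. CCA1 (LOC4344703), a morning gene of the plant clock, read 409.8 on root 1 and 4838 on root 2, OsPCL1 (LOC4326391), an evening gene, 4705 and 319.6, OsPRR73 2126 and 6521, and DTH7 669 and 2839. OsPRR1 (897 and 400.1) and OsPRR95 (1625 and 970.4) differed less, and GI was at 6929.9 and 7295. The ammonium transporter gene AMT1-2 (LOC4330008) read 3470.3 and 104, the phosphate transporter gene OsPht1;2 (LOC4331637) 1289.9 and 36.3, and the heat shock factor gene HSF11 (LOC4334080) 70.9 and 2614. Between the endosperm arrays the largest log2 difference of these 7 clock genes was 0.99 (OsPRR1), with CCA1 at 490.1 and 475. Harvest time was not recorded, so a difference in it was not tested.

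All 5 tests of this pattern, photosystem and light harvesting genes lower in embryo than in endosperm and uneven between the arrays of endosperm and of root, were chosen after the result was seen. For green tissue carried over with the endosperm, the 100 probe sets brightest in leaf had a median embryo minus endosperm log2 difference of -0.956 (0.07 against endosperm 1, -1.74 against endosperm 2), so this explanation cannot be told apart from the others, because the 2 endosperm arrays give different answers. Scaling of the seed arrays was argued against by a list median no closer to 0 than -1.81, and a difference in the scaling of the 2 arrays of a tissue by a ratio of 0.0799. For leaf tissue carried over, 8 of 100 leaf-bright genes on endosperm 2 and 6 on root 1 were under 1 percent of their leaf signal. These were too low for leaf as sampled at the photosystem list's shares of leaf signal, 18.6% and 30.3%. Yet the 100 genes had a median of 11.6% of leaf on endosperm 2 against 2.38% on endosperm 1, and 32.4% on root 1 against 8.85% on root 2. The count under 1 percent also replaced a first measure after both were seen. Whole-leaf carry-over had met that first one, with 59 and 82 of 100 genes at no less than 50% of the needed level. The measures disagree, so leaf carried over was not decided. Another green tissue, or light reaching these samples, may also give the pattern and stays open as untested.

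The test of the second pattern, leaf and root differing at 5935 probe sets, was written before its value was seen. Unequal 3-prime to 5-prime RNA quality could give such differences, as the Gapdh ratio was 26.3 and 29.1 in leaf but 2.04 on root 1 and 24.0 on root 2. Of the 5935 calls, 92.8% kept direction and 2-fold size against root 2 alone and 96.2% against root 1 alone. The first share passed the limit set beforehand for counting against RNA quality. That limit was set aside, because the calls had been made with both root arrays, so these shares decide little. A fit without root 1 sets leaf against root 2, whose ratio was close to that of leaf, but it rests on that 1 root array. With the Gapdh ratio as a covariate 2942 probe sets were higher and 1955 lower, against 3274 and 2661 as given. Of the variation of the ratio within tissues 98.9% lay between the 2 root arrays, so the covariate rests on that pair. With root 2 as the only root array of a ratio close to leaf, RNA quality and organ cannot be told apart as sources of these calls. The organ itself stays open as untested.

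The 3 tests of the third pattern, probe sets higher in the seedling than in both leaf and root, were written before their values were seen, but a level-matched odds ratio was added to the seed test before its value was seen, because both sets are defined against the same leaf and root arrays. For scaling of the seedling arrays, the lowest count under other scalings was 127 of 252, between the 2 limits set, so the count does not decide. It came with spike-in scaling, under which sizes hardly moved. The heat shock median was 1.05 against 1.08 as given over leaf, and 0.85 in both over root. That of the LEA list was 2.37 against 2.38 over leaf, and -0.16 in both over root. The lower count therefore does not show that scaling made the pattern. For unequal 3-prime to 5-prime RNA quality, the count was 317 with root 1 alone, past the limit set for arguing against it. This does not decide, because leaving out either root array also raised the count higher in seedling than in leaf, which compares no root array. For transcripts of the developing seed in the seedling, 73 of the 252 (29.0%) were embryo- or endosperm-preferred against 13.3% of the others (odds ratio 2.67, Fisher's exact p = 7.91e-11). The level-matched odds ratio was 1.85, so part of the excess went with shared signal levels and part remained after matching. That value lay under the limit set and its uncertainty was not computed, so this explanation stays undecided. The 3 days of age and the plant parts outside leaf and root may also matter and stay open as untested.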
